A study of Homo sapiens with 4 samples.

How the data were processed

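Human BE(2)C neuroblastoma cells with a MYCN open reading frame were transfected with siCon or siMYCN and with a control or let-7a miRNA mimic, and polyA RNA was sequenced 48 hours later, per the labels. Groups were taken from the sample labels, with 1 library in each of the 4 groups. The labels give no replicate numbers.

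The deposited table holds 19837 rows with a natural log value per library, and the base was settled from the values: exp(x) - 1 summed to between 855811 and 862049 in each library, where base 2 would give between 143211 and 147588. The back-transformed values are therefore treated as TPM-like. HISAT 0.1.6, Salmon 0.3.2 and the build GRCh38 are named in the submitters' processing notes, with no role or order. The annotation, any filter and the log step are not given in the sources used here. TPM-like values keep no read depth, so no counting error could be given. Reads shared between overlapping genes, paralogs or antisense genes may be divided between them in ways that cannot be checked from gene-level values.

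Rows for vector sequences (11) were set apart, leaving 19826 gene rows. Of these rows, 28 carried gene names turned into calendar dates; they were counted and not named. GENCODE release 29, on GRCh38, supplied coordinates and 3' UTRs, and 18700 rows matched one of its symbols. Genes with a mean over the 4 libraries of at least 5 were tested (9324 genes), of which 8914 (95.6%) had a 3' UTR.

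The choices in this paragraph were made before the data were examined. The main test was limma-trend on log2(value + 1), with siRNA and mimic as additive terms. The fit leaves 1 residual degree of freedom, the interaction, which stands in for error, so its p-values assume that the effects add. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted by direction. Because the design is unreplicated, p-values set each effect against the departure from additivity among these 4 libraries, and single pairs have no test. Limma moderated each gene's departure toward a trend over all genes, with 4.30 prior degrees of freedom beside the 1 residual. Its SEs and p-values thus rest largely on other genes. A rule of size counted genes at least 1.5-fold the same way in both of the pairs that share no library, and the interaction was counted at 2-fold. Gene lists fixed from general knowledge were established and wider predicted let-7 targets, collagens with let-7 sites, RNA interference machinery, MYC-activated and MYCN-repressed genes, noradrenergic, mesenchymal-like and neuronal differentiation genes, G1/S and G2/M genes, p53 targets, interferon, unfolded protein stress, cholesterol synthesis, ribosomal protein, mitochondrial and control genes, and fibroblast, epithelial and blood markers. A list's median was placed among 10000 random lists matched on mean expression in 20 bins, and site classes of the longest 3' UTR were also matched on 3' UTR length. That joint matching used 10 expression bins and 5 length bins, numbers that were not among the choices made beforehand. Adjusting limma p-values over the members of a list alone was not among those choices either. It was done for each list and treatment, with no correction across lists. Named genes were the 10 highest and 10 lowest by the smaller of the 2 pairs' log2 fold changes for each treatment, the 5 highest and 5 lowest differences between the let-7a effects, up to 4 members of each list, and MYCN, LIN28B, HMGA2, DICER1, ARID3B, TRIM71 and IGF2BP1, IGF2BP2 and IGF2BP3. Some genes that this rule names are not reported here.

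The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 20, rescaling by median ratios, limma without a trend, other fold sizes, the 3' UTR of the longest coding sequence, matching on expression only, and each pair alone. Random lists in the alternatives numbered 2000. A list median was taken to have moved when it changed by more than the SD of the random lists' medians, since groups hold 1 library. Robust variance, leaving out genes with the word GTGAAAG and the alternatives for the MYCN level were chosen after seeing the data.

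All words of 7 bases (16384) were scanned in 3' UTRs for genes whose ranked effect differed, after 3' UTR length and GC content, with 200 shuffles of the genes' values. This scan was also chosen after seeing the data. The additive test was tested on simulated data over 9324 genes for the let-7a effect: it called 16.4% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 87.9% of those changed 4-fold, with 8 false calls. The simulation changed 67, 67 and 66 genes at these sizes, in additive data with noise drawn from the limma fit. The shares depend on those numbers and need not hold for the real let-7a effect. The word scan ranked 5 of 5 implanted words first over 8858 genes, with a log2 shift of 0.2 in independent noise of SD 0.35. Smaller shifts, such as medians of 0.014 against 0.093 for genes with GTGAAAG, were not simulated. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used with R 4.3.3 and limma 3.58.1.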

Results

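RNA was measured by polyA RNA sequencing in BE(2)C cells carrying a MYCN open reading frame. BE(2)C is a human neuroblastoma cell line. The cells received an siRNA, either a control (siCon) or one against MYCN (siMYCN), together with a miRNA mimic, either a control (miRCon) or let-7a, and were harvested 48 hours later. Each of the 4 combinations was represented by 1 library, so no group had a replicate and no difference between 2 libraries has a replicate check. The deposited values were natural logs, and after back-transformation they resembled TPM and are called TPM-like values. They summed to 858071 in siCon with miRCon, 862049 in siCon with let-7a, 855811 in siMYCN with miRCon and 859454 in siMYCN with let-7a. Read depth is unknown, because such values keep no depth. Between 14790 and 15294 genes had a value above 0 in each library. Transcripts of the mitochondrial genome took 31.6% and 32.1% of the total in the siCon libraries and 28.4% and 29.3% in the siMYCN libraries.

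The design crosses both treatments, and its series title concerns let-7 biogenesis and function in neuroblastoma. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The let-7a effect was seen in a pair of libraries with siCon and in another with siMYCN, and these pairs share no library. The siMYCN effect was likewise seen once with each mimic.

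MYCN, the transcription factor targeted by the siRNA, was only slightly lower with siMYCN. Its level was 1448.5 with siCon and miRCon, 1432.8 with siCon and let-7a, 1238.3 with siMYCN and miRCon and 1197.2 with siMYCN and let-7a. The change with siMYCN was -14.5% with the control mimic and -16.4% with let-7a. The log2 fold change over both pairs was -0.24 ± 0.047 (SE of the additive limma model, n = 4 libraries), with a Benjamini-Hochberg adjusted p of 0.0584. The let-7a mimic left MYCN at log2 fold changes of -0.016 with siCon and -0.049 with siMYCN. MYCN lies on chromosome 2 from 15940564 to 15947007 of GRCh38, on the plus strand. Its gene-level value can mix transcripts of the introduced reading frame with those of the cells' own gene, and these were not separated.

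**Figure D1:**
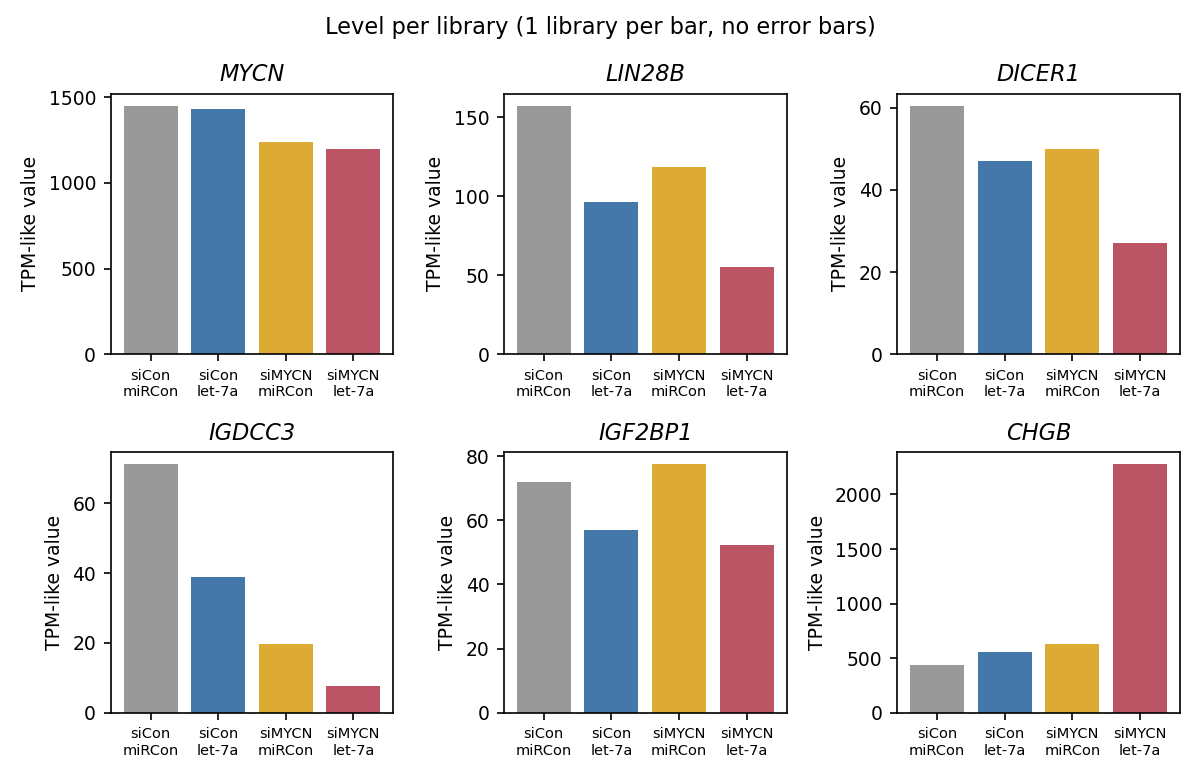
Level of 6 genes (TPM-like value, vertical axis from 0) in each of the 4 libraries, with 1 library per bar and no error bars. MYCN stood at 1448.5 and 1432.8 with siCon and at 1238.3 and 1197.2 with siMYCN, while LIN28B was lowest with siMYCN and let-7a, at 55.5.

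With the let-7a mimic, known let-7 targets were lower in both siRNA states. LIN28B, an RNA-binding protein that blocks let-7 maturation, was at 157 with miRCon and 96.5 with let-7a in siCon cells, and at 119 and 55.5 in siMYCN cells, which are log2 fold changes of -0.70 and -1.08. IGDCC3, a membrane protein of the immunoglobulin superfamily, had -0.86 and -1.28. DICER1, the RNase that cuts miRNA precursors, had -0.35 and -0.86, and the mRNA-binding protein IGF2BP1 had -0.33 and -0.56. ARID3A had -0.64 and -1.53, and the related ARID3B had -0.50 and -0.76. IGF2BP3 differed between the states, at 0.041 with siCon and -0.25 with siMYCN.

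The list of 36 measured established let-7 targets had 32 members with a let-7a effect below 0, and 29 that were lower in both pairs. Over both pairs, 42.3% of all tested genes had a let-7a effect above 0, against 4 of these 36. Its median log2 fold change was -0.18 with siCon and -0.32 with siMYCN. Each of these medians lay at percentile 0 among 10000 random lists matched on expression, which describes these libraries. By limma with Benjamini-Hochberg adjustment, 0 members passed over all genes tested and 7 passed, all lower, when adjusted over the list alone. These were LIN28B and IGDCC3 (both adjusted p = 0.012 in limma over the list alone), NAP1L1 (adjusted p = 0.0283), PRTG, IGF2BP1 and ARID3A (each adjusted p = 0.04) and DICER1 (adjusted p = 0.0429). Their log2 fold changes over both pairs ranged from -0.37 for NAP1L1, a histone chaperone, to -1.09 for ARID3A. HMGA2 and TRIM71, let-7 targets under the expression filter, had TPM-like values of 1.63 and 0.937 (HMGA2) and 2.71 and 2.10 (TRIM71) in siCon cells without and with let-7a, and 1.81 and 0.901 (HMGA2) and 2.65 and 1.21 (TRIM71) in siMYCN cells. IGF2BP2 was at or near 0 in every library, at 0.184 or less. A wider list of 79 measured predicted targets had medians of -0.090 with siCon and -0.16 with siMYCN, at percentiles 0.5 and 0.02. At a mean of at least 20 these were -0.049 and -0.12. Its members with a large shared change included RAB40C (-0.45 and -0.47), GXYLT1 (-0.43 and -0.57) and BACH1 (-0.65 and -0.40). No member of the wide list passed limma over all genes (0) or adjusted over the list alone (0).

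Genes grouped by the best let-7a seed site in their 3' UTR were lower as well. The 394 genes with an 8mer site (CTACCTCA) had a median let-7a effect of -0.057 with siCon and -0.11 with siMYCN, at percentiles 0.51 and 0 among lists without a site matched on expression and 3' UTR length. The 635 genes with a 7mer-m8 site had medians of -0.060 and -0.075, and the 667 genes with a 7mer-A1 site had -0.058 and -0.059, each of these 4 medians at percentile 0.01 or lower. All of these medians were closer to 0 with no filter and with rescaled values. With siCon and with siMYCN, those of 8mer genes were -0.0315 and -0.059 with no filter and -0.034 and -0.067 with rescaled values, those of 7mer-m8 genes -0.024 and -0.023 with no filter and -0.036 and -0.0336 with rescaled values, and those of 7mer-A1 genes -0.035 and -0.029 with no filter and -0.0336 and -0.019 with rescaled values. Of the 394 genes with an 8mer, 263 had a let-7a effect below 0 and 131 above 0. Among all tested genes, most were also below 0, with 42.3% above 0 over both pairs. Limma called 0 of the 8mer genes over all genes and 0 adjusted over the list alone. Site classes of 7 other miRNAs gave 21 comparable medians of the let-7a effect over both pairs, from -0.067 to -0.012, of which 3 lay under percentile 2.5 and 4 as far up at the other end. With siCon alone, 8 of these 21 classes lay outside the central 95%, and with siMYCN alone 2 did, so the percentiles of site classes overstate how rare a median is.

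**Figure D2:**
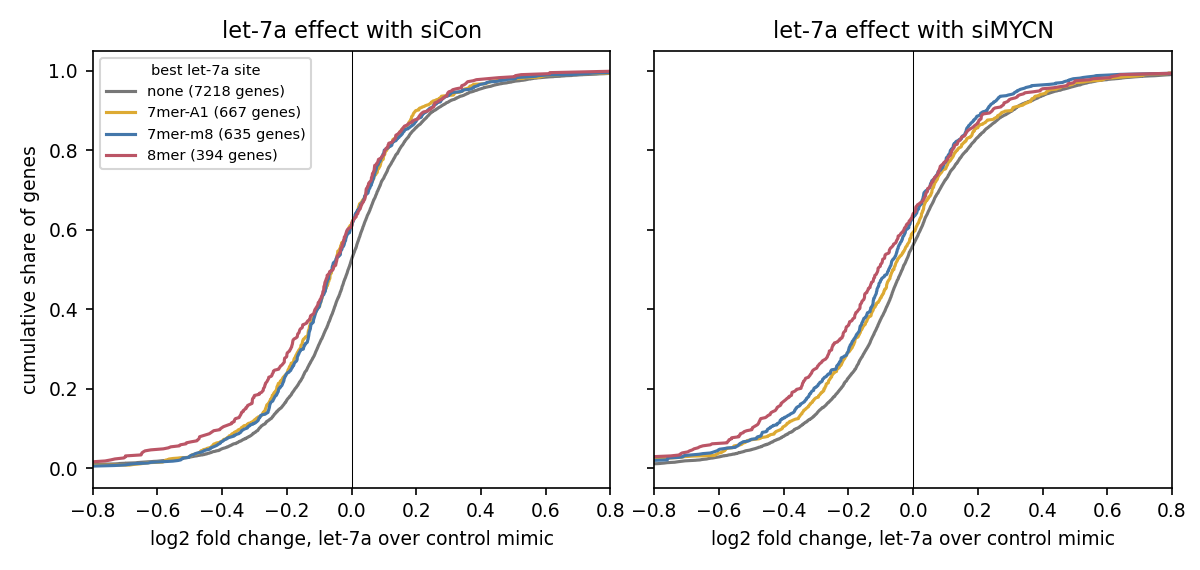
Cumulative share of genes (vertical axis) by log2 fold change of let-7a over the control mimic (horizontal axis), for genes grouped by their best let-7a site, with siCon on the left and siMYCN on the right. The curve of the 394 genes with an 8mer lies furthest to the left with siMYCN, where its median was -0.11.

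Over all 9324 tested genes, the let-7a effect had 0 genes called higher and 0 called lower by limma at an adjusted p of 0.05, and 697 at an unadjusted p under 0.05, of which 258 were higher and 439 lower. The smallest adjusted p was 0.663. The rule of at least 1.5-fold the same way in both pairs gave 19 higher and 24 lower genes. Independent pairs would give 3.79 and 6.47 if all genes varied alike. They did not: 5.31% of genes with a mean under 20 differed at least 2-fold between the let-7a effects, against 0.511% above. Noise alone can thus make low genes pass in both pairs more often than these figures allow. The excess does not by itself show a shared effect. Across genes, which are not independent replicates, the 2 let-7a effects had a Pearson r of 0.11 and a Spearman rho of 0.13. The higher genes with the largest shared change included ARL16 (1.17 with siCon and 1.88 with siMYCN), ZNF480 (1.12 and 1.22), ACYP2 (1.26 and 1.09), FAM195A (1.34 and 1.03), SNURF (0.99 and 1.07), CYB5D2 (1.09 and 0.86), FAM72B (0.85 and 1.09), MITD1 (1.88 and 0.85) and PLXNB3 (0.76 and 0.84). The lower genes, besides IGDCC3, were AC009060.2 (-3.09 and -4.40), POLR2J2 (-1.14 and -1.42), ST6GALNAC3 (-1.13 and -1.70), ACTR6 (-0.98 and -1.18), PRR13 (-0.88 and -1.05), SLC31A2 (-0.91 and -0.87), NDUFA13 (-0.99 and -0.80), LIN7B (-1.17 and -0.78) and AC004824.3 (-0.78 and -1.61). Apart from IGDCC3 and FAM195A, these named genes had a mean TPM-like value under 20, and at a mean of at least 20 the rule left 1 higher gene (FAM195A) and 4 lower genes (IGDCC3, LIN28B, STX10 and XYLT2), of which STX10 and XYLT2 were named after their values were seen.

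Among the other lists, the G2/M cell cycle genes were lower with let-7a. Their median was -0.071 with siCon at percentile 5.12, inside the central 95% of random lists, -0.16 with siMYCN at percentile 0.41, and -0.14 over both pairs at percentile 0.03, with CENPF, a kinetochore protein, at -0.32 and -0.38 and MKI67, a proliferation marker, at -0.27 and -0.22. The G1/S genes had a median of 0.043 with siCon and -0.22 with siMYCN. Neuronal differentiation genes had medians of 0.014 with siCon and 0.18 with siMYCN, with SYN1, a synaptic vesicle protein, at 0.31 and 0.54 and TUBB3, a neuronal tubulin, at 0.0765 and 0.48. The noradrenergic list had medians of 0.088 and -0.070, the latter becoming 0.11 at a mean of at least 20, and its members CHGB and CHGA, proteins of secretory granules, are described with the combined treatment. The RNA interference machinery had a median of -0.064 over both pairs at percentile 22.4, with ZCCHC11, which adds uridines to let-7 precursors, at -0.47 and -1.04. Ribosomal protein genes had a median of 0.066 at percentile 99.7 (0.0998 with rescaled values). Mitochondrial transcripts had 0.042 at percentile 93.1, control genes -0.0525 at percentile 20.2, cholesterol synthesis genes -0.048 at percentile 37.7, unfolded protein stress genes -0.012 at percentile 57.9, p53 targets -0.12 at percentile 11.3 (-0.030 with no filter), interferon genes 0.11 at percentile 91.9, MYC-activated genes -0.075 at percentile 2.1 (-0.041 with rescaled values), MYCN-repressed genes 0.23 at percentile 99.9 (0.11 at a mean of at least 20, with 5 members above and 4 below 0 in the 9 measured), mesenchymal-like genes 0.051 at percentile 79.7, and the 3 measured fibroblast markers -0.059 at percentile 35.1. None of these lists had a member called over all genes by limma (0 in each), and adjusted over the list alone the noradrenergic list had 2 higher (SATB1 and SLC6A2), the MYCN-repressed list 1 higher (EGR1) and the fibroblast list 1 lower (LUM).

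With siMYCN, limma called 193 genes higher and 127 lower at a Benjamini-Hochberg adjusted p under 0.05. DUSP6, a phosphatase that switches off ERK, rose from 3.51 to 21.7 with the control mimic and from 4.10 to 26.0 with let-7a, with log2 fold changes of 2.33 and 2.40 (adjusted p = 0.0206 by limma). CDKN1A, which encodes the cell cycle inhibitor p21, rose with log2 fold changes of 1.61 and 2.53, and CDH11, a cadherin, with 1.75 and 1.66. IGDCC3 fell with log2 fold changes of -1.80 and -2.22 (adjusted p = 0.0206 by limma), and the serotonin receptor subunit HTR3A with -2.25 and -2.81.

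The other genes that rose by the largest shared change were PRPF39 (2.69 and 3.20), ITM2A (1.57 and 2.12), DRGX (1.43 and 1.65) and LIN7B (1.29 and 1.67), together with PTPMT1 (2.28 over both pairs), the DNA repair gene ERCC1 (1.60 over both pairs) and DPYSL3 (1.42 over both pairs), a protein of growing neurites. Of these, PTPMT1 differed most between the pairs, at 1.56 with the control mimic and 1.44 more with let-7a, while ERCC1 was 0.21 and DPYSL3 0.17 higher with let-7a than with the control mimic. Those that fell included SCUBE1 (-1.67 and -2.30), TMEM245 (-1.46 and -1.39), the host gene of a miRNA, ARHGEF19 (-1.32 and -1.38), SUV420H2 (-1.93 and -1.32), the mitochondrial carrier SLC25A10 (-1.31 and -1.48), BPHL (-1.27 and -1.50) and the matrix protein SPARC (-1.24 and -1.64). All 20 genes chosen this way had an adjusted p between 0.0174 and 0.0493 by limma. The choice and the test used the same 4 libraries, so these p-values are no separate support. The rule of at least 1.5-fold the same way gave 266 higher and 150 lower genes. Independent pairs would give 46.3 and 19.8, again only if low and high genes varied alike. The 2 siMYCN effects had a Pearson r of 0.53 and a Spearman rho of 0.53 across genes. With values rescaled by median ratios, limma called 343 higher and 408 lower, so the split between directions depended on scaling. At a mean of at least 20 it called 310 higher and 196 lower. Without genes holding the word GTGAAAG in their 3' UTR, a setting chosen after the data were seen, it called 51 higher and 23 lower among 7923 genes. At an unadjusted p under 0.05 by limma, 2009 of these 7923 genes passed, against 2461 of 9324 in the main setting. The smallest adjusted p was 0.0333, against 0.0174. Why the calls were fewer was not tested, and they do not show that genes with the word carried most of the effect. With no expression filter, and with limma without a trend, it called 0 higher and 0 lower, with 2793 and 2221 genes at an unadjusted p under 0.05.

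**Figure D3:**
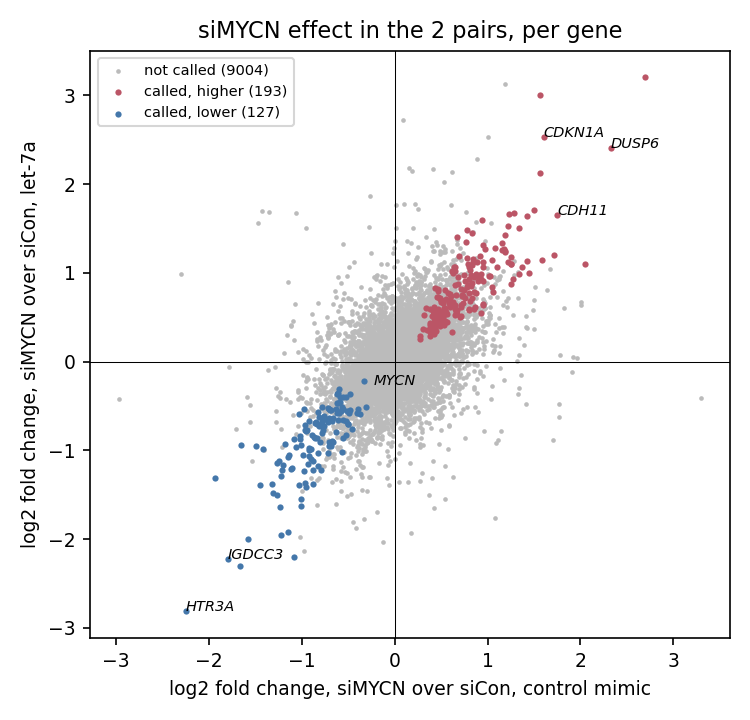
Log2 fold change of siMYCN over siCon per gene with the control mimic (horizontal axis) and with let-7a (vertical axis). Grey points are genes not called, red points the 193 called higher and blue points the 127 called lower by limma, and DUSP6 lies at 2.33 and 2.40 while IGDCC3 lies at -1.80 and -2.22.

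Genes given below in brackets as passing over their list alone were named after their values were seen, unless they are named elsewhere. Noradrenergic genes were lower with siMYCN. Of 18 measured members, 12 were lower in both pairs and the median over both pairs was -0.21 at percentile 0.01. Over all genes limma called 1 member higher and 2 lower, and adjusted over the list alone 4 higher (GATA2, TH, CHGB and SATB1) and 6 lower. Those called over all genes included GATA2 (0.47 over both pairs) and ISL1 (-0.68), which were named after their values were seen. SLC18A2, a vesicular monoamine transporter, had -1.02 and -1.98 and did not pass over all genes (adjusted p = 0.0605 by limma), while TH, which makes the precursor of dopamine, had 0.84 and 0.65. Neuronal differentiation genes went both ways, with 2 called higher and 1 lower over all genes, and 4 higher (DCX, SCG2, TUBB3 and SYP) and 5 lower (NEFH, NEFL, STMN2, GAP43 and CNTN1) adjusted over the list alone. DCX, a microtubule protein of young neurons, rose (0.95 and 1.32), SCG2 rose (0.38 and 0.60), and NEFH, the heavy neurofilament, fell (-1.08 and -0.87). The list's median was 0.093 at percentile 69.1, and became -0.0845 at a mean of at least 20.

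Ribosomal protein genes were higher with siMYCN, with a median of 0.24 at percentile 99.9. Of 23 measured, 16 were higher in both pairs, 5 were called higher over all genes and 13 adjusted over the list alone. Over both pairs, 58.3% of all tested genes had a siMYCN effect above 0. RPL32 rose (0.57 and 0.45), RPL11 rose (0.43 and 0.44) and RPL7 rose (0.40 and 0.52), and the others called were RPL23 (0.42 over both pairs) and RPL27 (0.35), named after their values were seen. With rescaled values the median was 0.17. Of 13 transcripts of the mitochondrial genome, 11 were lower in both pairs, the median was -0.14 at percentile 0.1, 1 was called lower over all genes and 9 adjusted over the list alone, and MT-CO1 fell (-0.33 and -0.22). Of 32 measured MYC-activated genes, 22 were below 0, with a median of -0.075 at percentile 0.33 (-0.14 with rescaled values). Limma called 2 of them lower over all genes, MDM2, the ubiquitin ligase of p53 (-1.11 and -1.21), and CAD, of pyrimidine synthesis (-0.70 and -0.55), and called 3 higher (CDK4, ODC1 and PTMA) and 5 lower (MDM2, CAD, MCM6, MCM4 and BOP1) adjusted over the list alone. The replication helicase genes MCM6 (-0.44 and -0.55) and MCM4 (-0.30 and -0.36) did not pass over all genes. Of 9 measured MYCN-repressed genes, CDKN1A rose and CLU, a secreted chaperone, fell (-1.14 and -1.91), and adjusted over the list alone 3 were higher (CDKN1A, CCNG2 and KLF2) and 3 lower (CLU, TGM2 and DKK3). The median of that list, 0.33, became -0.29 at a mean of at least 20 and -0.033 with no filter.

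G1/S genes had a median of -0.20 at percentile 0.05 with siMYCN, with 0 called over all genes and 1 higher adjusted over the list alone, CCNE1 (0.62 and 0.60). G2/M genes had -0.046 at percentile 5.1 (-0.11 with rescaled values), with 0 called either way and AURKA, a mitotic kinase, at -0.39 and -0.91. Of the p53 targets, CDKN1A rose while MDM2 and TP53I3 fell, and the median was -0.11, which became 0.11 at a mean of at least 20. IFI6 was the 1 interferon gene called (-0.84 and -0.86), of 4 measured. STARD4 was the 1 cholesterol gene called lower over all genes (-0.59 and -0.46), with 3 lower adjusted over the list alone (STARD4, FDFT1 and INSIG1) and a median of -0.078. Unfolded protein stress genes had a median of 0.13 with 0 called, the RNA interference machinery -0.0975 with 0 called, mesenchymal-like genes 0.15 (-0.0059 with no filter) with 0 called over all genes and 1 higher adjusted over the list alone (VIM), and control genes -0.069 with 0 called. The fibroblast list had 3 measured members and a median of -0.018, and the epithelial and blood lists had 0 members past the filter. The collagen list had 2 measured members, both with a let-7a effect below 0, and 0 called.

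The established let-7 targets had medians below 0 with siMYCN. The median was -0.033 with the control mimic at percentile 4.0 (-0.10 with rescaled values) and -0.13 with let-7a at percentile 0.3 (-0.027 with no filter), with 1 called higher over all genes (CCND1, a G1 cyclin, at 0.40 over both pairs, named after its values were seen) and 1 lower (IGDCC3), and 3 higher (CCND1, IRS2 and NAP1L1) and 5 lower (IGDCC3, LIN28B, INSR, SLC20A1 and CDK6) adjusted over the list alone. IRS2, an adaptor of insulin signalling, had 1.14 and 0.96, while INSR, the insulin receptor, had -0.53 and -0.50 and SLC20A1 -0.45 and -0.47. In the wide list, PYGO2 (0.80 and 0.78) and DUSP4 (0.74 and 0.80) rose, as did RBFOX2 (0.52 over both pairs, named after its values were seen), and TET3 fell (-0.82 and -0.73) among 3 called higher and 1 lower over all genes, with 7 higher and 3 lower (TET3, DUSP9 and HAND1) adjusted over the list alone, and its median of 0.054 lay at percentile 44.7 and was -0.0060 with rescaled values. The genes with an 8mer site had a median siMYCN effect of 0.054 with the control mimic and 0.0031 with let-7a, at percentiles 7.85 and 0, -0.016 and -0.0475 with rescaled values, and -0.0044 and -0.029 at a mean of at least 20.

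LIN28B, IGDCC3, DICER1 and IGF2BP1 were at their lowest when both treatments were combined. Of the 36 established targets, 26 had a lower let-7a effect with siMYCN than with siCon (72.2%, against 52.4% of all genes), and the median difference between the effects was -0.13 at percentile 1.53. DICER1 was at 60.5, 47.2, 50.1 and 27.1 in siCon with miRCon, siCon with let-7a, siMYCN with miRCon and siMYCN with let-7a. The 8mer genes had a median difference of -0.023 at percentile 2.22, the 7mer-m8 genes -0.030 at percentile 0.11 and the 7mer-A1 genes 0.0053 at percentile 33.7. Matched on expression only, the percentiles were 28.98 for 8mer, 13.38 for 7mer-m8 and 95.1 for 7mer-A1 genes, and 9 of 21 site classes of other miRNAs lay outside the central 95% for the same difference. With rescaled values the medians were -0.0051 for 8mer, -0.0124 for 7mer-m8 and 0.023 for 7mer-A1 genes, and at a mean of at least 20 that of 7mer-A1 genes was -0.011. CHGB was at 438, 557, 633 and 2275 in the same order, and CHGA at 687, 847, 489 and 1157. CDKN1A reached 63.1 with both treatments, against 9.55 with neither. The difference between the let-7a effects leaves no residual degrees of freedom, so it is a value with no test. At least 2-fold apart were 108 genes higher and 115 lower.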

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

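Of the tests below, the one on abundance was chosen after the result was seen, and the one on overlapping genes before.

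All 10 genes named for the largest differences between the 2 let-7a effects, 5 in each direction, had opposite signs with siCon and siMYCN. Choosing genes by that difference favours opposite signs, and the difference was not tested. The let-7a effect with siMYCN minus that with siCon, in log2, was 3.29 for SMIM10L1, 3.12 for PAM16, 3.04 for NT5C3B, 3.04 for SUN1 and 2.73 for TIMM23B. It was -3.70 for AC004824.2, -2.84 for FKSG70, -2.59 for COX4I1, a subunit of cytochrome c oxidase, -2.39 for LOXL3 and -2.25 for CPSF3L. Among all 9324 tested genes, 223 were at least 2-fold apart. Noise at low abundance may account for most of them: 5.31% of genes with a mean under 20 were this far apart, against 0.511% of those above, a ratio of 10.4. Reads assigned back and forth between genes that overlap on the same strand could add to this, since 10.1% of the genes (21 of 208 with coordinates) overlap another tabulated gene on the same strand, against a median of 6.25% in expression-matched lists, whose upper bound was 9.62%. That excess covers few of the genes. A true difference in response to let-7a between the siRNA states stays open and untested.

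Lists whose median had opposite signs in the 2 states stood out in the same way, and the difference was not tested. With siMYCN the let-7a effect had a median of -0.070 for noradrenergic genes, -0.22 for G1/S genes and -0.14 for unfolded protein stress genes, each above 0 with siCon. At a mean of at least 20 the noradrenergic median was 0.11, and the unfolded protein stress median with siCon was -0.024, so neither had opposite signs there. With let-7a the siMYCN effect had a median of -0.080 for p53 targets, -0.019 for unfolded protein stress genes, -0.033 for control genes and -0.10 for fibroblast markers, each above 0 with the control mimic. At a mean of at least 20 that of the unfolded protein stress genes with let-7a was 0.040, and with rescaled values those of p53 targets and control genes with the control mimic were -0.055 and -0.059, so these signs depended on the setting.

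Rows for vector sequences held values outside the comparisons. The kanamycin resistance row was at 194.9 in siCon with miRCon, 221 in siCon with let-7a, 195.6 in siMYCN with miRCon and 225.3 in siMYCN with let-7a, and the ampicillin resistance row was at 2.86 in siCon with miRCon, 2.92 in siCon with let-7a, 4.16 in siMYCN with miRCon and 2.30 in siMYCN with let-7a. The 9 other vector rows were at 0.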

How the results depend on the processing

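Leaving out genes that hold GTGAAAG, robust variance and the alternatives for MYCN were chosen after the result was seen. Replicates could not be paired because the labels give no replicate numbers and each group holds 1 library. The additive fit does compare each treatment within the states of the other. Read depth is unknown, so no limit of detection can be given. The let-7a effect had 0 genes called by limma in the main setting and in each alternative run. For siMYCN, limma called 343 higher and 408 lower with rescaled values, 310 and 196 at a mean of at least 20, 0 and 0 with no filter, 0 and 0 without a trend, and 51 and 23 without genes holding GTGAAAG, against 193 and 127. The last setting tested fewer genes, with 2009 at an unadjusted p under 0.05 by limma, against 2461 in the main setting. At 1.5-fold the same way in both pairs, the let-7a effect had 90 higher and 79 lower genes with no filter, 1 and 4 at a mean of at least 20, 8 and 9 with a pseudocount of 5, and 4 and 3 at 2-fold. The siMYCN effect had 406 and 271 with no filter, 105 and 74 at a mean of at least 20, 128 and 96 with a pseudocount of 5, and 36 and 28 at 2-fold. Genes 2-fold apart between the let-7a effects numbered 380 higher and 392 lower with no filter, 10 and 19 at a mean of at least 20, 35 and 39 with a pseudocount of 5, and 429 and 506 at 1.5-fold. The correlation of the 2 let-7a effects was 0.067 with no filter, 0.17 at a mean of at least 20 and 0.14 with a pseudocount of 0.1. That of the 2 siMYCN effects was 0.37 with no filter, 0.65 at a mean of at least 20 and 0.57 with a pseudocount of 5, and that of the additive effects was 0.033, 0.18 and 0.12 in the same settings and 0.067 with a pseudocount of 0.1. MYCN with rescaled values had let-7a effects of 0.0095 with siCon and -0.0055 with siMYCN, and siMYCN effects of -0.30 with miRCon and -0.31 with let-7a.

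The let-7a effect over both pairs, taken from either pair alone, ranged from -0.32 to -0.18 for established targets, from -0.16 to -0.090 for the wide list, from -0.11 to -0.057 for 8mer genes, from -0.075 to -0.060 for 7mer-m8 genes and from -0.059 to -0.058 for 7mer-A1 genes. Of 752 list medians recomputed, 42 changed sign. Those of MYCN-repressed genes for siMYCN did so at a mean of at least 20 and, over both pairs and with let-7a, with no filter. Those of 8mer genes for siMYCN did so with rescaled values and, in each pair, at a mean of at least 20. At a mean of at least 20, so did those of neuronal genes for siMYCN in each pair and over both, p53 targets for siMYCN over both pairs, noradrenergic genes for let-7a with siMYCN, cholesterol genes for let-7a with siCon, MYCN-repressed genes for let-7a with siMYCN (-0.0465), unfolded protein stress genes for let-7a with siCon (-0.024) and for siMYCN with let-7a (0.040), and 7mer-A1 genes for the difference between let-7a effects. With no filter, so did those of mesenchymal-like genes for let-7a over both pairs (-0.0127) and with siMYCN (-0.0026) and for siMYCN over both pairs (-0.0059), interferon genes for siMYCN over both pairs and for let-7a with siCon (-0.0001), p53 targets for let-7a with siCon and for the difference, unfolded protein stress genes for let-7a with siCon (-0.016) and over both pairs (0.018) and for siMYCN with let-7a (0.0077), control genes for let-7a with siCon (0.0096), fibroblast markers for siMYCN over both pairs (0.016) and cholesterol genes for the difference (-0.0055). With rescaled values, so did those of the wide let-7 list for siMYCN with let-7a and over both pairs, neuronal genes for siMYCN with miRCon (-0.0056), p53 targets for let-7a with siMYCN (0.011) and for siMYCN with miRCon (-0.055), unfolded protein stress genes for let-7a over both pairs (0.022), cholesterol genes for let-7a with siMYCN (0.019), and control genes for let-7a with siCon (0.0002) and for siMYCN with miRCon (-0.059). Matched on expression only, the percentiles that moved were 6.97 for 8mer genes for siMYCN over both pairs, 49.81 for 7mer-m8 genes and 65.95 for 7mer-A1 genes for siMYCN with let-7a, and 28.98 for 8mer genes and 13.38 for 7mer-m8 genes for the difference between let-7a effects. Of all 878 values recomputed, 722 stayed within the spread or within 1.5 times the count, 149 moved, and 7 changed sign where the reported median lay outside the central 95% of random lists. Except for filters and rescaling, which change the genes counted or the zero point, the cause was not tested.

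With no filter, the medians below moved. Those of the let-7a effect with siCon were 0.045 for p53 targets, -0.064 for fibroblast markers, -0.0315 for 8mer genes, -0.024 for 7mer-m8 genes and -0.035 for 7mer-A1 genes. Those of the let-7a effect with siMYCN were -0.25 for established let-7 targets, -0.059 for 8mer genes, -0.023 for 7mer-m8 genes and -0.029 for 7mer-A1 genes. Those of the siMYCN effect with miRCon were 0.011 for 8mer genes, 0.038 for 7mer-m8 genes and 0.045 for 7mer-A1 genes. Those of the siMYCN effect with let-7a were -0.027 for established let-7 targets, -0.15 for MYCN-repressed genes, 0.0325 for 7mer-m8 genes and 0.035 for 7mer-A1 genes. Those of let-7a over both pairs were -0.23 for established let-7 targets, -0.030 for p53 targets, -0.053 for 8mer genes, -0.0274 for 7mer-m8 genes and -0.034 for 7mer-A1 genes. Those of siMYCN over both pairs were -0.022 for established let-7 targets, -0.033 for MYCN-repressed genes, 0.0070 for interferon genes, 0.0355 for 7mer-m8 genes and 0.044 for 7mer-A1 genes. Those of the difference between let-7a effects were -0.098 for p53 targets and -0.011 for 7mer-m8 genes.

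At a mean of at least 20, the medians below moved. Of the let-7a effect with siCon, they were -0.049 for the wide let-7 list and 0.0125 for cholesterol genes. Of the let-7a effect with siMYCN, they were -0.12 for the wide let-7 list and 0.11 for noradrenergic genes. Of the siMYCN effect with miRCon, they were -0.16 for MYCN-repressed genes, -0.11 for neuronal genes and -0.0044 for 8mer genes. Of the siMYCN effect with let-7a, they were -0.45 for MYCN-repressed genes, -0.075 for neuronal genes, -0.072 for G2/M genes, -0.029 for 8mer genes and 0.071 for 7mer-m8 genes. Of let-7a over both pairs, they were -0.22 for established let-7 targets, 0.11 for MYCN-repressed genes, 0.14 for noradrenergic genes, 0.036 for neuronal genes and -0.0516 for 7mer-A1 genes. Of siMYCN over both pairs, they were -0.29 for MYCN-repressed genes, -0.0845 for neuronal genes, 0.11 for p53 targets and 0.0097 for 8mer genes. Of the difference between let-7a effects, they were -0.011 for 7mer-A1 genes.

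With a pseudocount of 5, the medians below moved. The let-7a effect with siMYCN had -0.093 for 8mer genes. Let-7a over both pairs had -0.071 for 8mer genes, -0.050 for 7mer-m8 genes and -0.0505 for 7mer-A1 genes. The difference between let-7a effects had -0.0876 for MYCN-repressed genes.

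With rescaled values, the medians below moved. In the let-7a effect with siCon, values were -0.034 for 8mer genes, -0.036 for 7mer-m8 genes and -0.0336 for 7mer-A1 genes. In the let-7a effect with siMYCN, values were -0.11 for the wide let-7 list, -0.0484 for MYC-activated genes, 0.13 for ribosomal genes, -0.067 for 8mer genes, -0.0336 for 7mer-m8 genes and -0.019 for 7mer-A1 genes. In the siMYCN effect with miRCon, values were -0.10 for established let-7 targets, 0.0031 for the wide let-7 list, -0.11 for MYC-activated genes, -0.26 for noradrenergic genes, -0.11 for G2/M genes, 0.12 for ribosomal genes, -0.22 for mitochondrial transcripts, -0.016 for 8mer genes, 0.0145 for 7mer-m8 genes and 0.0069 for 7mer-A1 genes. In the siMYCN effect with let-7a, values were -0.0049 for the wide let-7 list, -0.0475 for 8mer genes, 0.0004 for 7mer-m8 genes and 0.0090 for 7mer-A1 genes. In let-7a over both pairs, values were -0.076 for the wide let-7 list, -0.041 for MYC-activated genes, -0.11 for G2/M genes, 0.0998 for ribosomal genes, -0.051 for 8mer genes, -0.0304 for 7mer-m8 genes and -0.027 for 7mer-A1 genes. In siMYCN over both pairs, values were -0.19 for established let-7 targets, -0.0060 for the wide let-7 list, -0.14 for MYC-activated genes, -0.11 for G2/M genes, 0.17 for ribosomal genes, -0.028 for 8mer genes, 0.0059 for 7mer-m8 genes and 0.0051 for 7mer-A1 genes. In the difference between let-7a effects, values were -0.0051 for 8mer genes, -0.0124 for 7mer-m8 genes and 0.023 for 7mer-A1 genes.

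With the 3' UTR of the longest coding sequence, a single median moved. This was the siMYCN effect with miRCon, 0.0304 for 8mer genes.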

Other observations

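The tests below were chosen after the results were seen.

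In 3' UTRs, the word whose genes were lowest with let-7a was CTACCTC, the 7mer-m8 site of let-7, with a z of -8.36, the lowest of all words over both pairs, first with siCon (-5.28) and first with siMYCN (-8.22). With siMYCN the lowest word was GTGAAAG, with a z of -9.92 over both pairs, followed by TGTGAAA, and the highest was GACAGTA at 6.67. Of the 20 genes chosen by the largest shared siMYCN change, 1 of which had no 3' UTR matched, IGDCC3, which fell, and CDH11, which rose, held the word. The 1401 genes with the word had a median siMYCN effect over both pairs of 0.014, against 0.093 in lists matched on 3' UTR length and GC content.

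Genes with GTGAAAG in their 3' UTR lay below other genes with siMYCN. For being the lowest of all words by chance, 0 of 200 shuffles of the genes' values gave as large a z in size. The shuffles treat genes as independent, which they are not, so their spread may be too narrow and they cannot decide on chance. GACAGTA, at 6.67, also lay beyond every shuffle. It ranked 2nd highest with miRCon (5.47) and highest with let-7a (6.56), in pairs that share no library. Why GACAGTA stood out was not tested. GTGAAAG had the largest z in size. For 3' UTR length or GC content, the median lay at percentile 0 among matched lists. The scan that picked the word had already adjusted for both, so this matching is not a separate check. A fault of a single library was argued against by a z of -7.16 in the weaker of the pairs, which share no library. The shift was not alike in both: z was -11.01 with miRCon and -7.16 with let-7a. With miRCon the median siMYCN effect was -0.0081, against 0.1043 in matched lists. With let-7a it was 0.0354, against 0.1002. For the difference between the 2 pairs the word had a z of 3.51, the 7th highest, and no shuffles were run for it. Why the shift was smaller with let-7a was not tested. Seed pairing of an siRNA guide directed at MYCN may be a source: the MYCN transcript holds TGTGAAAG once, in its 3' UTR, in exon 3, at 15946752 to 15946759 on chromosome 2 of GRCh38. That stays open, since 7.8% of protein-coding transcripts of like length, and 3.99% of 3' UTRs of like length, hold it as well and the siRNA sequence is not given in the sources used here.

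The let-7a effect of genes with an 8mer or a 7mer-m8 site was lower with siMYCN than with siCon, with interaction medians of -0.023 and -0.030, while that of the 7mer-A1 genes was not (0.0053). Whether this stands apart from other genes depended on the matching. The percentiles were 2.22 (8mer) and 0.11 (7mer-m8) among lists matched on expression and 3' UTR length, but 28.98 (8mer) and 13.38 (7mer-m8) among lists matched on expression only. With rescaled values, which moved the median of all genes by 0.018, the medians were -0.0051 (8mer), -0.0124 (7mer-m8) and 0.023 (7mer-A1). With no filter that of 7mer-m8 genes was -0.011, and at a mean of at least 20 that of 7mer-A1 genes turned to -0.011. Long 3' UTRs changing more in that pair stay open, because 9 of 21 site classes of other miRNAs (42.9%) also lay outside the central 95% of lists matched on 3' UTR length. In the word scan, adjusted for 3' UTR length and GC content, CTACCTC ranked 3rd lowest for this difference (z of -4.10). TACCTCA ranked 22nd (-3.49). The words ACCGCGC (-4.24) and CACCGCG (-4.15), which are not let-7 sites, ranked lower, and no shuffles were run for this difference. siMYCN freeing let-7 already in the cells stays open too, since the let-7 groups differed in the siMYCN effect with the control mimic. The 8mer genes lay at percentile 7.85 (16.0 matched on expression only) and the established targets at 4.0. The 7mer-m8 genes lay at 67.7, the 7mer-A1 genes at 48.2 and the wide list at 48.7, which shows no lowering. More active let-7a mimic in that library stays open as well. The classes lay 3.03 (8mer), 1.67 (7mer-m8) and 1.30 (7mer-A1) times as far below matched genes with siMYCN as with siCon, but 1.78 (8mer), 0.909 (7mer-m8) and 0.586 (7mer-A1) times when matched on expression only. With 1 library per group, these cannot be told apart from a biological difference.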
